A study of Mus musculus with 8 samples.

How the data were processed

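Total RNA from bone marrow and fetal liver suspensions of wild-type and Col18a1 knockout mice was hybridised to Affymetrix mouse expression arrays, per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets. The authors made these intensities with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes, and the version is not given in the sources used here. The log2 of each deposited intensity was taken here before any test. RMA makes the distributions of the arrays alike, so a change that shifts most genes 1 way would be removed, and it compresses differences of dim probe sets. No detection calls were used here, so no probe set is called absent and low levels are given as measured.

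Groups were taken from the sample titles, with 2 arrays per group and 4 groups, and 2 littermates were pooled for each array. Of the probe sets, 34958 name 1 gene in the platform annotation, 932 name several and 9211 are unnamed here. Entrez identifiers of 34754 of the first kind were found in the RefSeq gene table (assembly GRCm38.p6) and 0 symbols changed. That table was used for names, chromosomes and which genes neighbour each other, and no coordinates are given because the array files name no genome build. For each of 18194 genes the probe set with the highest mean over the 8 arrays was kept, and the 13136 genes at 5 or more (log2) on at least 2 arrays were tested. Selection by brightness can pick a probe set that does not speak for others of the gene.

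The tests were made in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 8 arrays, with default empirical Bayes moderation (4 residual and 4.48 prior degrees of freedom) and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The contrasts were taken from this model: knockout against wild-type in each tissue, the interaction, the average of both genotype differences, and fetal liver against bone marrow in wild-type arrays. Col18a1 was also tested over all probe sets with no filter. Differences are on the log2 scale with standard errors of the fit, and every printed adjusted p of a gene is from limma, two-sided.

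Gene lists (29 written by hand, plus ribosomal proteins and genes within 10 Mb of Col18a1 on its chromosome) were tested with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, over the 30 lists with at least 5 tested members. The sex-linked list had too few tested members for this. Camera with the correlation estimated per list and fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes, were alternatives. The design, lists, alternatives and rule for named genes were fixed before the data were examined. That rule takes, for each contrast, Col18a1, the 10 largest positive and 10 largest negative called genes whose groups do not overlap (with the smallest unadjusted p added up to 5 per direction), leaving out clone-type symbols and sex-linked genes, and up to 4 members of each list with the largest moderated t. Fewer are named in the text, and those to name were picked from the rule's genes after their values were seen. The sex-linked genes Xist, Eif2s3y, Kdm5d and Uty, which the rule leaves out, were also named after their values were seen, because they separate the fetal liver pools.

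The fit was tested on simulated data for the 13136 genes, 200 of them changed in each of 10 rounds. Means were those of the real groups, with the knockout mean of the tissue set to wild-type before the changes. Spreads were not those of the single genes but were drawn from the prior of the fit, the same in all groups. Since the fit assumes this model, a share of false calls near the threshold is close to built in. For bone marrow, 50.7% of 1.5-fold, 91.3% of 2-fold and 99.5% of 4-fold changes were recovered, and 5.35% of the calls were false. For fetal liver the shares were 49%, 92.4% and 99.7%, with 4.75% false. The simulation holds no hidden difference between pools, such as sex or cell content, and says nothing about those. Of 100 unshifted lists, 3 in bone marrow and 1 in fetal liver had a p under 0.05 (camera, preset correlation). Noise was independent between the simulated genes. This count therefore does not bear on lists whose genes move together, such as the megakaryocyte list, with an estimated correlation of 0.408.

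Alternatives covered the filter, the choice of probe sets, normalization, the variance model, array weights, the replicate number as a block, the arrays in the fit, the threshold and each array left out in turn. Added after the data were seen were leaving out chromosomes X and Y, the megakaryocyte list mean as a covariate in bone marrow, additive terms for tissue and genotype, and an adjustment without the sex-linked genes. Single-array ratios of 3 prime to 5 prime control probe sets were computed as a sign of RNA quality. Probe sets that name several genes or none were left out of the gene tests.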

Results

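Gene expression was measured in total RNA from hematopoietic tissue of mice that carried intact Col18a1 alleles (wild-type) or lacked the gene (knockout). The sample titles give C57B6/J for the wild-type arrays. Col18a1 encodes the alpha chain of type XVIII collagen, a heparan sulfate proteoglycan of basement membranes whose C-terminal fragment is endostatin. Cell suspensions came from the bone marrow of 3-month-old males and from fetal liver at embryonic day 14.5, the sex of the embryos being unstated. Each of the 8 arrays held RNA pooled from 2 littermates, with 2 arrays for each of the 4 combinations of tissue and genotype. Median intensities lay between 40.8 and 42.6 on the 8 arrays. Arrays of 1 group correlated across genes at r = 0.992 to 0.997, genes not being independent replicates, and no pair of arrays was identical, 28 to 96 of 45101 probe sets having the same value on both. The small number of arrays limits the precision of every value, and the p-values of genes measure the spread between pools of mice only. Camera and Fisher's exact test weigh genes against other genes instead. The fit gave each gene 1 spread for all 4 groups. The median SD was 0.063 in wild-type and 0.069 in knockout bone marrow, and 0.083 and 0.106 in fetal liver. Standard errors may thus be too small in fetal liver and too large in bone marrow.

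The targeted gene was lower in knockout arrays of both tissues. The array holds 2 probe sets for Col18a1, an _s_at and an _at probe set. In bone marrow, the _s_at probe set of Col18a1 stood at 7.84 ± 0.01 (log2, SD, n = 2) in wild-type and 5.81 ± 0.26 (n = 2) in knockout, a difference of -2.03 ± 0.14 (SE; adjusted p = 0.00268, limma over all probe sets). In fetal liver the same probe set stood at 9.12 ± 0.08 in wild-type and 8.12 ± 0.07 in knockout, a difference of -1.003 ± 0.14 that missed the threshold over all probe sets (adjusted p = 0.0546, limma) and passed it over the genes tested (adjusted p = 0.0315, limma). The _at probe set of Col18a1 differed by -1.34 ± 0.13 in bone marrow (adjusted p = 0.0227, limma) and by -1.62 ± 0.13 in fetal liver (adjusted p = 0.0034, limma). Leaving out 1 array left the differences between -2.22 and -0.95 but ended calls of Col18a1: over all probe sets, that of the _s_at probe set in bone marrow without wild-type replicate 1 (adjusted p = 0.0809, limma) and that of the _at probe set in bone marrow without any 1 of the bone marrow or knockout fetal liver arrays (adjusted p = 0.0577 to 0.282, limma). Over the genes tested, the fetal liver call was lost without any 1 of the wild-type arrays of either tissue or knockout fetal liver replicate 1 (adjusted p = 0.0815 to 0.11, limma). Col18a1 lies on chromosome 10. Whether either probe set matches the deleted part of the gene is not given in the sources used here, so the remaining signal does not measure the completeness of the deletion.

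**Figure D1:**
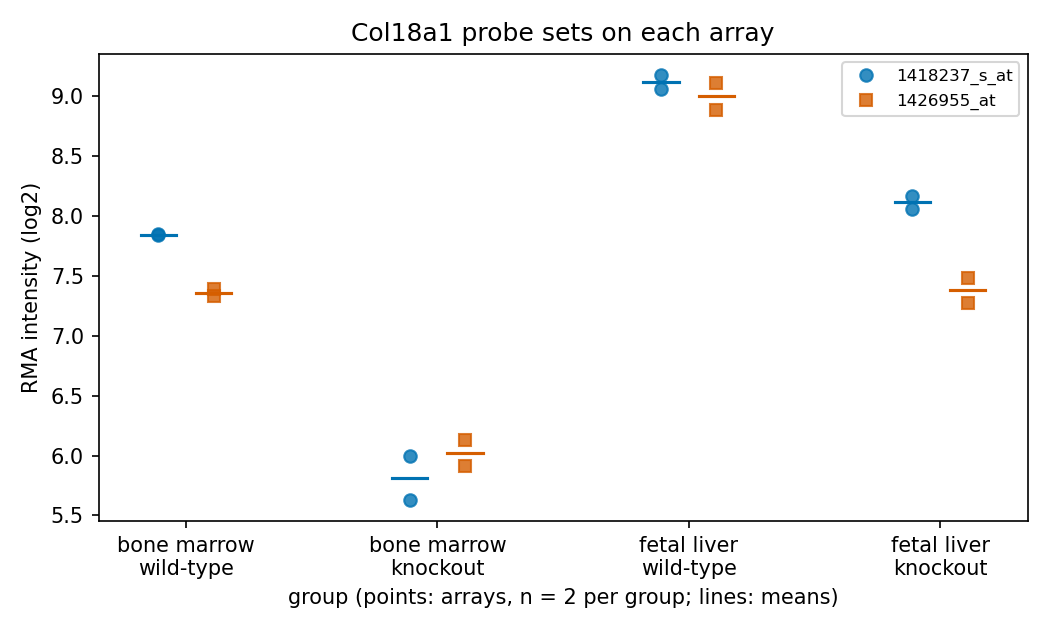
Log2 intensity of the 2 Col18a1 probe sets on each of the 8 arrays, with points for arrays and lines for the means of 2 arrays per group. In both tissues the knockout arrays lie below the wild-type arrays, for example at means of 5.81 against 7.84 for the _s_at probe set in bone marrow.

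The first comparison asked how loss of Col18a1 altered expression in adult bone marrow. Genes of megakaryocytes, the bone marrow cells that shed platelets, were lower in knockout bone marrow. Of the 19 tested members of the megakaryocyte and platelet list, 19 had a negative difference, 11 fell at an adjusted p under 0.05 over all genes and 17 fell when adjusted over the list alone. The median of the list was -1.04 (log2). Tubb1, the platelet beta-tubulin, fell by 1.46 ± 0.13 (SE; adjusted p = 0.00682, limma). Vwf, which encodes von Willebrand factor, fell by 1.44 ± 0.16 (adjusted p = 0.0111, limma), and the chemokine gene Ppbp fell by 1.05 ± 0.10 (adjusted p = 0.00682, limma).

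**Figure D2:**
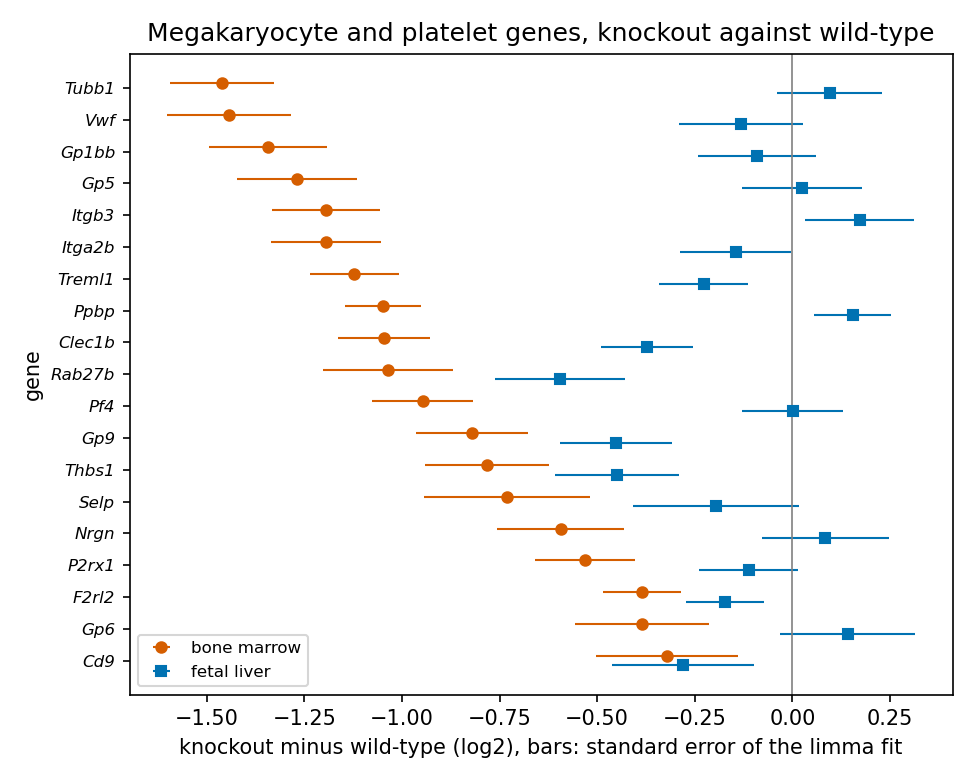
Difference of knockout from wild-type (log2, horizontal axis) for each of the 19 tested megakaryocyte and platelet genes (vertical axis) in bone marrow and in fetal liver, with bars for the standard error of the limma fit on 2 arrays per group. All 19 points lie below 0 in bone marrow, with a median of -1.04, and in fetal liver 12 lie below 0, with a median of -0.13.

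In all, 54 of 13136 genes differed between knockout and wild-type bone marrow, 6 higher and 48 lower (adjusted p under 0.05, limma). Lgr4, a receptor for R-spondins, fell by 2.15 ± 0.09 (adjusted p = 7.43e-05, limma), from 7.71 to 5.55, on its brighter probe set. A dimmer Lgr4 probe set lay near 4.38 in wild-type, which may be too low to show such a fall, and this was not tested. Among the other genes that fell most were Kalrn, by 1.61 ± 0.14, Pde5a, by 1.57 ± 0.16, Cald1, by 1.54 ± 0.16, Alox12, the platelet 12-lipoxygenase, by 1.41 ± 0.12, Mfap3l, by 1.41 ± 0.18, and Myom1, by 1.37 ± 0.15.

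Matrix and adhesion genes were also among those that fell in knockout bone marrow. Of 27 tested stroma and bone genes 2 fell, or 5, beside 1 that rose, when adjusted over the list alone, with Col1a1 falling by 1.22 ± 0.17 and Col1a2, its partner chain in type I collagen, by 0.76 ± 0.12. In the list of basement membrane genes, 2 of 25 fell (3 when adjusted over the list alone), with Nid1 falling by 0.83 ± 0.12 and Col4a2 by 0.74 ± 0.12. The list of integrins had 3 of 18 members that fell, and the same 3 when adjusted over the list alone, namely Itgb3, by 1.19 ± 0.14, Itga2b, by 1.19 ± 0.14, and Itga6, by 0.77 ± 0.10. Itgb3 and Itga2b, which form the platelet fibrinogen receptor, are also members of the megakaryocyte list. Slamf1, the SLAM marker of the stem and progenitor list, fell by 1.04 ± 0.14, while the other 25 of 26 members of that list did not pass. The embryonic globin gene Hbb-y fell by 0.62 ± 0.10 at a low level, from 5.23 to 4.61.

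The 6 genes that rose in knockout bone marrow included immediate early and inflammatory genes. Ptgs2, which encodes the inducible cyclooxygenase, rose by 1.52 ± 0.24 (adjusted p = 0.0488, limma), and the neutrophil chemokine gene Cxcl2 rose by 1.38 ± 0.15 (adjusted p = 0.0111, limma). Jun rose by 1.31 ± 0.16 and Dusp1 by 0.96 ± 0.12 (adjusted p = 0.013 for each, limma). Hnmt, the histamine N-methyltransferase gene, rose by 0.66 ± 0.10 and the transcription factor gene Foxo1 by 0.64 ± 0.10. In the immediate early and stress list 2 of 29 members rose, or 5 when adjusted over the list alone, and Atf3 differed by 0.87 and Fos by 0.95 without passing over all genes. In the inflammatory cytokine list 2 of 24 members rose, or 5 when adjusted over the list alone, and Ccl4 differed by 0.60 and Osm by 0.71 without passing.

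Of the 30 gene lists tested in bone marrow with camera at a preset correlation, 15 passed, 8 of them lower and 7 higher. None passed with an estimated correlation, where the lowest adjusted p was 0.0803. The lower lists were megakaryocyte and platelet (adjusted p = 8.49e-42 preset, and 0.0803 with an estimated correlation), stroma and bone (median -0.28), basement membrane (-0.18), endothelial (-0.15), angiogenic signalling (-0.12), B lineage (-0.11), integrins (-0.07) and Wnt components (-0.07). The higher lists were inflammatory cytokines (median 0.20), monocyte and macrophage (0.17), mast cell, basophil and eosinophil (0.15), interferon response (0.13), immediate early and stress (0.09), heme synthesis (0.09) and cell cycle (0.06). The interferon list mean differed by 0.12 between genotypes, against 0.18 between the wild-type and 0.17 between the knockout pools. For stroma and bone the list mean differed by -0.26, against 0.26 between the wild-type and 0.02 between the knockout pools. No single member of the endothelial, angiogenic, B lineage, Wnt, monocyte, mast cell, interferon, heme or cell cycle lists passed over all genes. A two-sided t test of list means between pools was added after the data were seen. With the spread of the bone marrow pools alone none of the 30 lists passed (lowest adjusted p = 0.0921, t test). With that of all pools the megakaryocyte, B lineage, basement membrane, integrin, Wnt, immediate early and inflammatory lists passed. The 15 lists that did not pass, at adjusted p of 0.0855 to 0.974, were erythroid, globins, neutrophil, T and NK cell, stem and progenitor, dendritic and MHC class II, plasma cell, hepatocyte, heparan sulfate proteoglycans, matrix proteases, hypoxia and glycolysis, collagen biosynthesis, apoptosis and p53, ribosomal proteins and the neighbours of Col18a1. The count of 54 genes depended on single arrays, being 2 without either knockout array, 8 without wild-type replicate 1 and 76 without wild-type replicate 2, while the megakaryocyte median stayed between -1.13 and -0.82 with 1 array left out. It was 3 when only the 4 bone marrow arrays were fitted.

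The second comparison addressed loss of Col18a1 in fetal liver, where 42 of 13136 genes differed, 16 higher and 26 lower (adjusted p under 0.05, limma), 4 of them sex-linked. At an unadjusted p under 0.05 the fetal liver difference was broader than that in bone marrow (limma). It then took in 2890 genes, 1037 higher and 1853 lower, against 886 in bone marrow, where 656.8 are expected by chance in each. The gap was smaller where the spread could differ between the tissues. It was 1928 against 1337 genes with each tissue fitted alone and 2091 against 1442 with array weights (limma). Settings with 1 spread for both tissues left it wide, such as 3251 against 965 with no filter on low values. The amino acid transporter gene Slc7a3 rose by 1.07 ± 0.13 (adjusted p = 0.0315, limma), Gdap10 by 1.05 ± 0.09 (adjusted p = 0.00295, limma) and the nuclear non-coding RNA Malat1 by 0.81 ± 0.10 (adjusted p = 0.0356, limma). Colec12, a scavenger receptor gene, fell by 0.95 ± 0.11 (adjusted p = 0.0171, limma), from 7.15 to 6.20, and Tead2, a transcription factor gene of the Hippo pathway, fell by 0.91 ± 0.13 (adjusted p = 0.041, limma). Ago2, which encodes an Argonaute protein of RNA interference, rose by 0.74 ± 0.10, Ubn2 by 0.73 ± 0.10 and the histone gene H3f3a by 0.68 ± 0.10. Tmem154 fell by 0.95 ± 0.10, Fndc4 by 0.91 ± 0.09, Mapk8ip1 by 0.86 ± 0.09 and Pdgfc, a platelet-derived growth factor gene, by 0.83 ± 0.13. Sex-linked here means Xist and the genes of chromosome Y. Of the 38 called genes outside these, 3 lie on chromosome X, where 394 of the 13136 tested genes lie. Of the same 38 genes, 13 lay under 6 (log2) in both groups, among them Spib, at 4.03 and 4.82, Adam8, at 4.18 and 5.09, and S100g, at 5.23 and 4.29.

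The pools of the 2 fetal liver genotypes differed in sex-linked expression. Xist, the RNA of the inactive X chromosome, stood at 11.04 and 11.22 on the wild-type arrays and at 4.97 and 4.77 on the knockout arrays, where the male bone marrow arrays lay between 4.61 and 5.03. The Y-linked gene Eif2s3y stood at 3.29 and 3.00 on the wild-type arrays and at 9.38 and 9.42 on the knockout arrays. Kdm5d rose by 4.06 ± 0.15 and Uty by 4.24 ± 0.20 (adjusted p = 5.38e-06 and 4.07e-05, limma). Genotype and the sex-linked difference thus covered the same arrays, and a fetal liver difference cannot be assigned to either from these arrays alone. The count of 42 was 5 without knockout replicate 1, 1010 without knockout replicate 2, and 14 and 6 without wild-type replicates 1 and 2. It was 9 without either wild-type bone marrow array and 13 without either knockout one. Centring each array on its median moved the lower share of the calls from 61.9% to 42.1%.

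**Figure D3:**
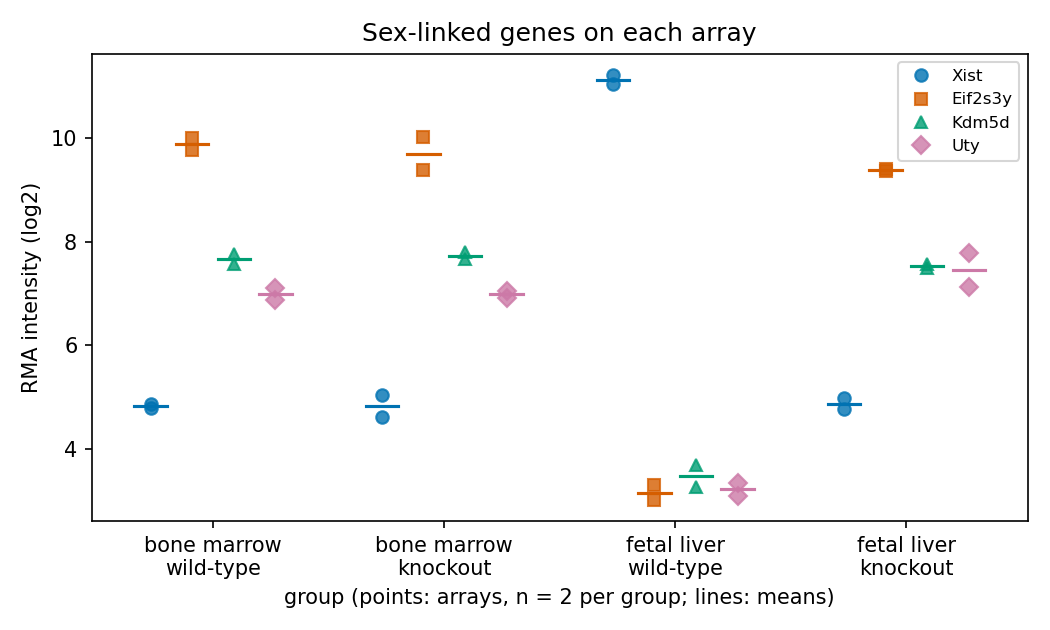
Log2 intensity of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 8 arrays, with points for arrays and lines for the means of 2 arrays per group. Xist lies at 11.04 and 11.22 on the wild-type fetal liver arrays and between 4.61 and 5.03 on the other 6 arrays, and the Y-linked genes run the opposite way.

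Of the 30 lists, the erythroid list alone passed in fetal liver with the preset correlation. Its median was 0.10 with 18 of 24 members positive (adjusted p = 0.0202, camera), and its adjusted p = 0.811 with an estimated correlation. Over all genes 0 of its members rose, against 2 when adjusted over the list alone, with Ank1, an ankyrin of the red cell membrane, at 0.41 and Ermap at 0.39. The megakaryocyte list had a median of -0.13 in fetal liver, with 12 of 19 members negative, 0 called and an adjusted p of 0.377 (camera). Clec1b differed by -0.37 and Gp9 by -0.45 without passing. The other lists had adjusted p of 0.068 to 0.839 (camera), and their called members were Spib of the B lineage list, Adam8 of the matrix protease list and Epcam of the hepatocyte list, which fell by 0.77 ± 0.12.

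The interaction tested whether the genotype difference itself differed between the tissues, as fetal liver minus bone marrow. It was called for 12 of 13136 genes, 9 positive and 3 negative, 4 of them sex-linked (adjusted p under 0.05, limma). At an unadjusted p under 0.05 the balance was the reverse, with 805 positive and 1251 negative. The megakaryocyte genes Tubb1 and Ppbp had interactions of 1.56 ± 0.19 and 1.20 ± 0.14 (adjusted p = 0.0471 and 0.0353, limma), having fallen in bone marrow only by test, with fetal liver differences of 0.10 and 0.15. All 19 tested members of the megakaryocyte list had positive interactions, with a median of 0.68 (adjusted p = 4.72e-16, camera, and adjusted p = 0.235 with an estimated correlation). Lgr4 had an interaction of 2.18 ± 0.13 (adjusted p = 0.000296, limma), with fetal liver means of 9.78 in wild-type and 9.81 in knockout. Alox12 and Myom1 gave 1.39 ± 0.17 and 1.58 ± 0.21, and Zbed6 gave 1.08 ± 0.14. Negative values were found for Mapk8ip1, at -1.01 ± 0.12, and for Rfc2, a subunit gene of replication factor C, at -0.98 ± 0.13. For Col18a1 the interaction was 1.03 ± 0.18 and missed the threshold (adjusted p = 0.0929, limma), and it was -0.28 on the _at probe set. Since the fetal liver pools also differed in sex-linked expression, this test carries that difference. Without Xist and the genes of chromosome Y 1 gene was called, the other 7 being lost to the adjustment alone (adjusted p = 0.0717 for each, limma) with unaltered differences. The count of 12 was 20 without wild-type bone marrow replicate 2, 80 without knockout fetal liver replicate 2 (20 positive and 60 negative) and 5 with any 1 of the other arrays left out.

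Averaged over both tissues, 26 of 13136 genes differed between the 4 knockout and the 4 wild-type arrays, 6 higher and 20 lower (adjusted p under 0.05, limma), 4 of them sex-linked. Without Xist and the genes of chromosome Y 14 genes were called, 8 more then having an adjusted p of 0.0516 to 0.0548 (limma) with unaltered differences. The average includes the fetal liver difference, where genotype and sex-linked expression covered the same arrays, so it carries that difference too. Col18a1 fell by 1.52 ± 0.09 (adjusted p = 0.000252, limma). The megakaryocyte genes Clec1b, by 0.71 ± 0.08, Treml1, by 0.67 ± 0.08, Rab27b, by 0.82 ± 0.12, and Vwf, by 0.79 ± 0.11, fell as well, the last with differences of -1.44 in bone marrow and -0.13 in fetal liver. Of the 19 members of that list 5 fell, or 16 when adjusted over the list alone, with a median of -0.62, no list test having been planned for the average. Proser2 fell by 1.10 ± 0.16, Gucy1b1, a subunit gene of soluble guanylate cyclase, by 0.78 ± 0.10, and Sytl4, a granule secretion gene, by 0.78 ± 0.10. Cxcl2 rose by 0.90 ± 0.11, Gdap10 by 0.73 ± 0.06 and Slc7a3 by 0.72 ± 0.10. The tissues contributed unequally. Clec1b, Rab27b and Gucy1b1 differed by -1.05, -1.04 and -1.23 in bone marrow against -0.37, -0.59 and -0.34 in fetal liver. Gdap10 and Slc7a3 differed by 0.40 and 0.37 in bone marrow against 1.05 and 1.07 in fetal liver. Across genes, the 2 genotype differences, which share no array, correlated at r = 0.014, with a Spearman rho of -0.007. The count was 7 without either knockout bone marrow array or without knockout fetal liver replicate 1, and 171 without knockout fetal liver replicate 2. Without wild-type replicates 1 and 2 it was 11 and 55 for bone marrow and 11 and 9 for fetal liver.

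As a scale for the genotype differences, wild-type fetal liver was set against wild-type bone marrow. Here 8663 of 13136 genes differed, 5148 higher and 3515 lower in fetal liver (adjusted p under 0.05, limma), around a median of all genes of 0.14. Hepatocyte genes led the higher genes. All 31 tested members of the hepatocyte list rose, with a median of 7.28 (adjusted p = 2.18e-16, camera, and adjusted p = 0.0606 with an estimated correlation). Alb, serum albumin, was higher by 10.08 ± 0.31 and Afp, alpha-fetoprotein, by 10.04 ± 0.12. The embryonic globin genes Hbb-y and Hbb-bh1 were higher by 9.18 ± 0.10 and 7.15 ± 0.16.

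The lists of mature blood cells were lower in fetal liver. All 27 members of the B lineage list fell, with a median of -4.80 (adjusted p = 2.15e-17, camera, and adjusted p = 0.017 with an estimated correlation, the single list that then passed), led by Ms4a1, the CD20 gene, at -7.79 ± 0.21, Pou2af1, at -7.95 ± 0.16, and Ebf1, at -6.52 ± 0.28. All 27 neutrophil genes fell, with a median of -3.41 (adjusted p = 0.0614 with an estimated correlation), and Chil3 differed by -10.33 ± 0.11. The eosinophil genes Prg2 and Epx differed by -8.07 ± 0.15 and -6.64 ± 0.11, in a list of which 13 of 13 fell. Megakaryocyte genes were lower in fetal liver as well, with 13 of 19 members falling and a median of -0.72 (adjusted p = 9.91e-05, camera, and adjusted p = 0.283 with an estimated correlation). Macrophage genes went both ways, with Marco at 4.33 ± 0.15 and Cd163 at -3.75 ± 0.12. In all, 17 lists passed with the preset correlation. Endothelial, stroma and bone, basement membrane and collagen biosynthesis lists were higher, with medians of 1.27, 0.96, 1.45 and 1.32. Lower lists also included dendritic and MHC class II (-2.09), interferon response (-1.21), inflammatory cytokines (-1.02), immediate early and stress (-0.99), T and NK cell (-0.45), monocyte and macrophage (-0.67), plasma cell (-1.63) and apoptosis and p53 (-0.34). Col18a1 was higher in wild-type fetal liver by 1.27 ± 0.13 (adjusted p = 2.72e-05, limma). The pools of this comparison differed in sex-linked expression too, and in age, and their mean log2 ratios of 3 prime to 5 prime signal for beta-actin and Gapdh were 1.39 and 1.64 in fetal liver against 0.757 and 0.618 in bone marrow.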

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

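The tests of explanations in this part were all chosen after the results they bear on had been seen. The interaction and list tests were planned, and the test of probe sets that name no single gene was added later.

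The interaction test picked out 12 genes whose genotype difference differed between the tissues, as fetal liver minus bone marrow (limma). The sex-linked genes were Xist at -6.26, Eif2s3y at 6.44, Kdm5d at 4.00 and Uty at 4.24. The others were Lgr4 at 2.18, Myom1 at 1.58, Tubb1 at 1.56, Alox12 at 1.39, Ppbp at 1.20, Zbed6 at 1.08, Mapk8ip1 at -1.01 and Rfc2 at -0.98. By camera with the preset correlation, 8 lists also differed, with median interactions of 0.68 for megakaryocyte and platelet, 0.38 for endothelial, 0.23 for angiogenic signalling, 0.18 for stroma and bone, 0.13 for basement membrane, 0.10 for hypoxia and glycolysis, -0.33 for inflammatory cytokines and -0.37 for mast cell, basophil and eosinophil genes. None of the 8 passed with an estimated correlation, where the lowest adjusted p was 0.235. Among the 4299 probe sets that name no single gene, which the report's comparisons do not use, 4 were called in fetal liver and 0 in bone marrow (limma, 161 there at an unadjusted p under 0.05). These 4 differed by 7.03, 5.74, 4.35 and -1.05. The positive differences were about as large as those of the Y-linked genes in fetal liver. Which genes these probe sets measure is not given here, so sex of the pools cannot be told apart from genotype for them.

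The fetal liver calls include 4 sex-linked genes, and the sex of the pooled embryos was weighed as their source. On the wild-type arrays 3 Y-linked genes lay -4.89 (log2) from the male bone marrow arrays, and the knockout arrays lay -0.04 from them, which is consistent with female wild-type and male knockout pools. Sex is argued against for Col18a1, which differed by -2.03 in bone marrow, where all pools were male. For the other 37 calls it cannot be told apart from genotype, because by these genes each genotype has pools of 1 sex, and 2 of the 37 moved the same way in bone marrow at an unadjusted p under 0.05 (limma), where 1.30 are expected by chance. RNA degradation also stays open for the calls outside the sex-linked genes: the mean log2 ratio of 3 prime to 5 prime signal for beta-actin and Gapdh was 0.21 higher in knockout arrays, at 1.83 and 1.62 against 1.39 and 1.64 in wild-type, so the groups overlap. The ratio for 18S RNA parted the genotypes, being lower in knockout, at -1.83 and -1.56 against -1.27 and -1.35 in wild-type. Fetal liver arrays, with higher ratios for beta-actin and Gapdh than bone marrow arrays, also had lower 18S ratios (-1.27 to -1.83 against -0.50 to -0.71). A lower 18S ratio thus need not oppose a higher ratio of these genes. One sign of RNA quality does therefore move with genotype, as chance gives for 1 in 3 such values.

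The fall of megakaryocyte genes in knockout bone marrow may reflect fewer megakaryocytes or platelets in those suspensions, since 19 of 19 members were lower, but lower expression within these cells would give that count too and was not tested. Of the 19 members 3 are on another list, and 17 were at 6 or more (log2) in wild-type fetal liver. An incomplete flush that lowers all cells of the marrow lining alike was weighed over members at 6 or more in wild-type bone marrow. The stroma and bone median lay 0.75 above the megakaryocyte median (95% bootstrap interval over genes 0.43 to 0.93). The endothelial median lay 0.93 above it (0.47 to 1.09), so these listed genes did not fall alike. The bootstrap takes genes as independent and holds no spread between pools. Estimated correlations were 0.408 for the megakaryocyte, 0.187 for the stroma and 0.175 for the endothelial list. Whether the listed members come from lining cells alone was not tested, so such a flush stays open. The members spread by an SD of 0.35 and 0.31, and 0.35 for megakaryocyte genes, and Col1a1 at -1.22, Esam at -0.92 and Col1a2 at -0.76 lay near the megakaryocyte genes, so a loss of some lining cells stays open. The level limit and the bound of this test were rewritten after first values were seen, the differences over all members being 0.76 and 0.88. RNA degradation stays open, the mean 3 prime to 5 prime ratio differing by -0.0602 with overlapping groups. Variation between pools, such as in large cells held back by the mesh, stays open as well. The list mean differed by -0.93 between genotypes, against 0.31 between the wild-type pools and 0.02 between the knockout pools. In a t test of list means, two-sided and adjusted over the 30 lists, this passed with the spread of all pools (adjusted p = 0.0193) and by fry (adjusted p = 0.0137), and missed with the spread of the bone marrow pools alone (adjusted p = 0.145). A difference in handling shared by both pools of a genotype was not tested. An earlier form of this test used the gap between the wild-type pools alone (a median of 0.29 over the list, 0.11 in knockout) and left the question open too.

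The rise of Jun, Dusp1, Cxcl2 and Ptgs2 in knockout bone marrow could come from handling before lysis, which induces immediate early and heat shock genes. The median of the immediate early and stress list was 0.0897, with 21 of 29 members positive, so it decides nothing. The list mean differed by 0.28 between genotypes, against 0.005 between the wild-type and 0.03 between the knockout pools. In the t test of list means it passed with the spread of all pools (adjusted p = 0.0193) and missed with bone marrow pools alone (adjusted p = 0.0921). A rise of the list does not tell handling from genotype. Of the heat shock genes, Hspa1a at 1.41 and Hspa1b at 1.16 were higher, while Dnajb1 at -0.04 and Hsph1 at 0.01 hardly differed. None of these passed (adjusted p = 0.501 to 0.994, limma). Ccl3 at 1.04, Fos at 0.95, Atf3 at 0.87, Egr1 at 0.42 and Hspb1 at -0.20 did not pass either. All these genes were named after their values were seen. An effect of genotype on these genes stays open as well.

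For the average over tissues, the splits comparable with the real one are too few for a share under 0.05. They are the 18 that part the arrays of each tissue 2 and 2, of which 1, the real one, called as many as 26 genes (limma). The highest of the others, which swaps the genotypes in 1 tissue and so equals the interaction, called 12. Another 16 splits part each tissue 3 and 1, with a standard error 1.15 times larger, and called 0 genes each. The model with 1 mean per tissue and side of the split was chosen after additive terms for tissue and genotype had called 0 genes for every split (1266 at an unadjusted p under 0.05 for the real one, limma), and the limit to 18 splits was set after all 34 had been counted. Of the 26 genes 4 are sex-linked, which this count does not separate from genotype.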

How the results depend on the processing

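The counts of genes changed with the threshold, the probe sets, the variance model and the arrays in the fit, and the cause was not tested unless given here. Counts are for bone marrow, fetal liver, interaction and average in that order, against 54, 42, 12 and 26 (limma). Trend and robust moderation gave 97, 409, 68 and 92, array weights 109, 9, 6 and 11, and an unadjusted p under 0.05 with a 1.5-fold change 152, 257, 567 and 53. Fitting 1 tissue alone, with fewer arrays, gave 3 and 4. With no filter on low values fetal liver gave 14 and the interaction 5. For the average, the stricter filter gave 51, single probe sets 14 and quantile normalization 41. Quantile normalization or centring gave 19 for the interaction. Without Xist and chromosome Y the interaction gave 1 and the average 14, and the same 1 and 14 when p-values were kept and only the adjustment left these genes out (chosen after seeing the data), so beside the 4 removed genes the adjustment took 7 and 8. The tissue comparison, at 8663, gave 17475 over single probe sets and 5690 by unadjusted p and fold.

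Replicate numbers did not pair the pools (correlations of same-numbered deviations across genes of -0.004 and -0.062). With the replicate number as a block the counts were 34, 4, 6 and 8.

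Chosen after seeing the data, leaving out chromosomes X and Y gave 34 in fetal liver. The megakaryocyte list mean as a covariate, with the list left out, gave 0 in bone marrow (241 at an unadjusted p under 0.05, limma), where 43 calls lay outside the list. That mean was 9.32 and 9.01 in wild-type and 8.23 and 8.25 in knockout, so it nearly coincides with genotype, the unscaled standard error grew 4.36 times, and the 0 excludes nothing. Additive terms for tissue and genotype gave 0 for the average (1266 at an unadjusted p under 0.05, limma, lowest adjusted p = 0.144).

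Lists passing, at 15 in bone marrow, 1 in fetal liver, 8 for the interaction and 17 between tissues, were 0, 0, 0 and 1 with an estimated correlation and 8, 0, 0 and 28 by fry, with 2 in fetal liver under the stricter filter. With an estimated correlation the megakaryocyte median of -1.04 in bone marrow had an adjusted p of 0.0803.

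Leaving out 1 array, the lone one being assumed to vary like the others, gave 2 to 76 genes in bone marrow, 5 to 1010 in fetal liver, 5 to 80 for the interaction, 7 to 171 for the average and 7392 to 8972 between tissues. Lists ranged over 12 to 15, 0 to 3, 6 to 10 and 17 to 18. Col18a1 ranged from -2.22 to -1.85 and -1.45 to -1.23 in bone marrow and from -1.06 to -0.95 and -1.73 to -1.51 in fetal liver, with highest adjusted p of 0.0809, 0.282, 0.16 and 0.0313 (limma), and the megakaryocyte median from -1.13 to -0.82. For named genes past the threshold, the values over alternatives that stayed past it and those that did not numbered 378 and 169 in bone marrow, 286 and 196 in fetal liver, 133 and 77 for the interaction and 178 and 106 for the average, while all 593 stayed between tissues and none changed sign. The Col18a1 interaction, not called, turned to -0.28 without _x_at and _s_at probe sets, which leaves its other probe set. No background calls were used, so differences of dim genes may be understated.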

Other observations

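The tests and gene choices in this part were made after the data had been seen. Of the 54 bone marrow calls, 33 had the same sign in fetal liver, and 11 of them an unadjusted p under 0.05 in fetal liver (limma). By chance 29.2 and 7.24 are expected, so the overlap is near that background. Among the 11, by their fetal liver differences, were Clec1b at -0.37 and Rab27b at -0.59 of the megakaryocyte list. Gng11 at -0.44, Mfap3l at -0.61, Itga6 at -0.24 and Cxcl2 at 0.43 were also among them. Col18a1 was called in both tissues, where 0.173 shared calls are expected of independent lists. At an unadjusted p under 0.05 in both tissues, 80 genes were lower against 71.7 expected and 21 higher against 29.8.

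X-linked genes that are known to escape X inactivation had lower values in knockout fetal liver, with Kdm6a at -0.57, Ddx3x at -0.41, Eif2s3x at -0.31, Utp14a at -0.28 and Kdm5c at -0.19. None of the 5 passed (adjusted p = 0.0739 for Kdm6a, limma). In bone marrow the same genes lay between -0.02 and 0.08.

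Knockout fetal liver replicate 1 was lowest of the fetal liver arrays in the B1 repeat control, with an intensity of 2608, against 6127 on the other knockout array and 8440 and 6713 on the wild-type arrays. The second principal component, with 1.93% of the variance, parted the fetal liver genotypes, with knockout arrays at -21.6 and -6.44 and wild-type arrays at 15.7 and 11.7. On the fourth, with 0.721%, knockout fetal liver replicate 2 lay at -15.0 and the other fetal liver arrays between 2.85 and 8.61. The bioB spike-in control stood at 8.40 to 8.53 on bone marrow arrays and at 9.20 to 9.51 on fetal liver arrays.

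Alleles of another strain carried along with the targeted locus could make neighbours of Col18a1 differ in both tissues. Of 218 genes within 10 Mb, 2 moved the same way in both tissues at an unadjusted p under 0.05, against 98 of 12917 other genes (Fisher's exact test, two-sided, p = 0.683). The odds ratio of 1.21 has a 95% interval of 0.144 to 4.55, which leaves the question open. Timp3 and Ank3, both within that distance, fell in bone marrow by 0.90 ± 0.11 and 1.02 ± 0.15 (adjusted p = 0.0135 and 0.0328, limma) but are not among those 2, with fetal liver differences of 0.07 and 0.17 that did not pass.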
